A study of Homo sapiens with 4 samples.

How the data were processed

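RNA bound to chromatin was sequenced from 4 libraries of K562 cells, 2 of wild-type genotype and 2 of genotype SF3B1 K700E, per the labels. The labels call the cells immortalized epithelial, whereas K562 is commonly described as an erythroleukemia line. Per the treatment text that all 4 samples share, expression of the modified allele was induced with doxycycline (1 µg/ml) and cells were harvested after 4 days. The labels do not say separately whether the wild-type cells carried an inducible allele or received doxycycline. Per the labels' protocols, the cells were fractionated in buffers with 25 µM α-amanitin, which stops RNA polymerase II. The RNA was depleted 3 times of polyadenylated RNA and then of ribosomal RNA, and libraries were made with a SMARTer low-input kit.

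Per the run logs deposited with each sample, the authors aligned trimmed read pairs with STAR 2.7.10a in a single pass to GRCh38.p12, with an index holding 353424 junctions of GENCODE release 27 and with 1887 more from release 22 added at mapping. The deposited junction files give counts of reads across each splice junction, uniquely and multiply mapped, with no normalization, per the file headers of the runs and the fixed column order of STAR. They also give the longest overhang of any read across the junction. The files used here hold junction counts and run logs only, so unspliced nascent RNA, polymerase positions and retained introns were not analysed here. The labels state no strand for the kit, and the strand of each junction came from its splice motif.

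The counts used were uniquely mapped reads over junctions on the main chromosomes. Junctions numbered 455586 in any library, and 99.7% of the 188468 annotated ones were found in GENCODE release 29, which assigned them to genes. Reads over introns of more than 1 gene made up 3.98% of annotated-junction reads and were left out of the gene totals. Percent spliced in (PSI) was the share of a junction's reads among all reads leaving the same donor, or, for donors, among all reads entering the same acceptor. Junctions needed a GT/AG, GC/AG or AT/AC motif and 10 unique reads over the 4 libraries, and clusters needed at least 2 such junctions. The reference acceptor of a donor was its annotated junction with the most reads over all libraries.

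Junction use was tested with the quasi-likelihood fit and diffSpliceDGE of edgeR 4.0.16 in R 4.3.3, with group as the only term, TMM scaling and Benjamini-Hochberg adjustment at 0.05. The log2 change of a junction in that test is relative to the other junctions of its cluster. Reads over annotated junctions were summed per gene, filtered with filterByExpr and tested with edgeR's quasi-likelihood test, again with Benjamini-Hochberg adjustment. Values per gene are CPM, these reads scaled by library total and TMM factor. The standard error of a gene's log2 change was its absolute value divided by the square root of the quasi-likelihood F. It therefore carries no evidence beyond the p-value. Groups are given as mean ± SD with n = 2 per group. Gene lists were tested with camera in limma 3.58.1 at a preset correlation of 0.01, with an estimated correlation and with fry as checks. The 18 lists were targets of SF3B1-mutant cryptic splicing, erythroid, megakaryocyte, myeloid, lymphoid and epithelial markers, heme and iron, RNA polymerase II elongation, U2 snRNP and spliceosome, replication stress and DNA repair, DNA replication, R-loop factors, mitosis, p53 targets, the integrated stress response, SIN3, HDAC and H3K4 methylation, nonsense-mediated decay and NF-κB targets. Library-level shares were compared by an exact permutation test over the 6 assignments of 4 libraries, 2-sided, whose smallest possible p is 0.333. The share of upstream sites among called acceptors was compared with Fisher's exact test.

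The design, lists, window of 10 to 30 nt, alternatives and naming rule were fixed before the data were examined. The rule named, with 1 junction per gene, the 15 unannotated and 5 annotated acceptors with the largest rise in mean PSI and up to 5 donors, among called junctions with at least 100 cluster reads and with both mutant libraries on the same side of both wild-type libraries. It named the 10 genes with the largest rise and the 10 with the largest fall among called genes above the median expression with the same separation, all that qualified where fewer did, and also SF3B1, list members that passed, and target-list genes with a tested upstream acceptor. Of these, 1 acceptor and 1 gene are not used here. A name outside this rule is stated to have been chosen after its values were seen. A group at 0 was given a floor of 3 counts over the group, and folds against it are lower bounds. Intervals are 95% Wilson intervals, and intervals and floors cover counting error only, since PCR reads carry no molecular identifiers.

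Each test was run on simulated counts with known changes, drawn from the real means and library sizes. Junction changes were placed only in minor junctions of their cluster with more reads than the median tested junction (36 for acceptors, 35 for donors). All junctions were drawn at a common dispersion. Recovery for junctions with fewer reads was not simulated and may be lower. For acceptors of a shared donor the test recovered 82% of 8-fold and 17% of 3-fold changes, with 0 false calls. For donors of a shared acceptor it recovered 78% of 8-fold and 16% of 3-fold changes, with 1 false call. For genes it recovered 90% of 4-fold and 31.3% of 2-fold changes, with 8 false calls, and of 18 lists it found the 1 changed list and no other. Alternatives covered read minimums of 1 and 30, size factors, limma voom with diffSplice, DESeq2 1.42.0 for genes, multiply mapped reads, noncanonical motifs (given the strand of canonical junctions sharing an end, a rule set after the data were seen), a wider window, libraries thinned to equal depth, each library left out, and the replicate number as a block. Added after the data were seen were a junction test with the cluster total as offset, a crossed pairing of replicates, and gene tests without regional runs of genes. The reference held no genome sequence, so splice-site and branch-point sequences were not analysed here.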

Results

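Reads across splice junctions of chromatin-bound RNA were compared between 2 wild-type and 2 SF3B1 K700E libraries of K562 cells. SF3B1 is the U2 snRNP subunit that holds the branch-point region during recognition of the 3′ splice site, and K700E is its recurrent hotspot substitution in myeloid neoplasms. The series title concerns RNA polymerase II elongation and replication stress in splicing-factor mutants, and its design line names wild type against SF3B1 K700E. The libraries held 3582592 and 3687513 uniquely mapped junction reads in wild type, and 4304213 and 5322414 in SF3B1 K700E. They listed 261341 and 255549 junctions in wild type and 283563 and 302820 in SF3B1 K700E. Across genes, log CPM correlated with Pearson's r of 0.963 and 0.965 within the genotypes and 0.933 to 0.946 between them, a description only since genes are not independent replicates. The labels do not say that replicates are separate cultures, so p-values measure the spread between these samples, which may be technical.

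Spliced reads of SF3B1 itself (ENSG00000115524.15, GRCh38 chromosome 2, 197389784 to 197435091) were 956 ± 84.2 CPM in wild type and 774 ± 101 CPM in SF3B1 K700E (mean ± SD, n = 2). The log2 change was -0.31 with a standard error of 0.22 and did not pass (edgeR adjusted p 0.747). Junction counts carry no base calls, so the allele itself could not be read from these files.

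SF3B1 K700E cells took acceptors just upstream of the annotated one. In the radixin gene RDX, which ties actin to the plasma membrane, an acceptor 14 nt upstream took 0 of 66 wild-type reads and 42.1% ± 11.2 of the mutant reads. In SAFB2, a chromatin- and RNA-binding scaffold factor, PSI of an acceptor 13 nt upstream rose from 0.962% ± 1.36 to 29.7% ± 2.50. Over all 226 tested unannotated acceptors 10 to 30 nt upstream, in 208 genes, median PSI was 2.18% in wild type and 12.7% in SF3B1 K700E.

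Among 23366 junctions in 10916 clusters that share a donor, 31 acceptors in 29 genes rose and 1 fell (edgeR diffSpliceDGE with Benjamini-Hochberg adjustment), against 574 up and 167 down at an unadjusted p under 0.05. With limma voom 9 rose and 6 fell, against 442 up and 433 down unadjusted, so the excess of rises depended on the method. There 15 of the 22 named junctions, donors included, lost their call. Of the 31, 25 were unannotated and 15 had 0 wild-type reads. The 1 that fell, an unannotated junction on chromosome 2 from 131209820 to 131545045 with no gene assigned, went from 6.25% ± 0.478 (23 of 370 reads) to 0 of 331 reads (edgeR adjusted p 0.0260). It was chosen for mention after its values were seen. The number of increased acceptors was 11 without wild-type replicate 1, 11 without wild-type replicate 2, 6 without SF3B1 K700E replicate 1 and 5 without SF3B1 K700E replicate 2. The decreased one was not called without SF3B1 K700E replicate 1 or without SF3B1 K700E replicate 2, where the count was 0 with 184 and 193 down at an unadjusted p under 0.05 (edgeR), and limma voom called 6 decreased with all libraries.

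In NONO (chromosome X, intron 71297048 to 71297360), a paraspeckle RNA-binding protein, the acceptor 16 nt upstream rose from 0.739% ± 0.0424 to 14.1% ± 1.33 (edgeR adjusted p 0.0118). TNPO3, which imports SR proteins into the nucleus, used an acceptor 17 nt upstream in 0 of 102 wild-type reads, a limit of 2.94%, and in 21.8% ± 2.61 of the mutant reads, at least 7.43-fold higher (edgeR adjusted p 0.0240). TPR, the nuclear pore basket protein, used one 17 nt upstream in 0 of 119 wild-type reads and 19.3% ± 5.6 of mutant reads, at least 7.67-fold higher. In SRSF4, an SR splicing factor, the risen acceptor lay 4854 nt upstream, inside intron 4 of a transcript with 8 exons. That transcript is annotated as a target of nonsense-mediated decay. The acceptor went from 0 of 125 reads to 20.6% ± 10.8, at least 8.57-fold higher (edgeR adjusted p 0.0209). This share is of reads leaving that donor, not of all SRSF4 RNA.

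PHGDH catalyses the first step of serine synthesis. It used an acceptor 188 nt upstream in intron 6 (chromosome 1, 119734767 to 119735106) in 0 of 173 wild-type reads and 34.2% ± 3.50 of the mutant reads, at least 19.7-fold higher (edgeR adjusted p 0.000549). ACSM3, a mitochondrial acyl-CoA synthetase, used an acceptor 14 nt upstream in intron 4 (chromosome 16, 20777581 to 20780699) in 0 of 482 wild-type reads and 13.4% ± 0.220 of mutant reads, at least 21.5-fold higher (edgeR adjusted p 0.000190). NADSYN1, the NAD synthetase, used one 3021 nt upstream in 0 of 110 wild-type reads and 18% ± 5.92 of mutant reads, at least 6.61-fold higher. DIP2A, a gene proposed to act in acetyl-CoA metabolism, rose from 4.55% ± 2.01 to 43.3% ± 10.4 at an acceptor 17 nt upstream (edgeR adjusted p 0.0118).

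ADGRV1, an adhesion receptor of sensory hair cells, rose from 2.57% ± 1.20 (6 of 204 reads) to 57.2% ± 8.61 (60 of 103) at an acceptor 10 nt upstream in intron 27 (edgeR adjusted p 0.00268). IQGAP3, a cytoskeletal scaffold, rose from 0.990% ± 1.40 to 21.3% ± 2.16 at 9 nt upstream. MINDY4, a deubiquitinase, rose from 2.71% ± 0.798 to 25.2% ± 0.0134 at 14 nt upstream. In PILRB, an immunoglobulin-like receptor, an acceptor 7 nt downstream rose from 1.31% ± 0.294 to 21.5% ± 2.11, but the locus overlaps the readthrough gene STAG3L5P-PVRIG2P-PILRB and its gene is uncertain. For RDX (chromosome 11, 110257928 to 110258105) the 0 of 66 reads allowed up to 4.55%, so the rise was at least 9.26-fold (edgeR adjusted p 0.0118).

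**Figure D1:**
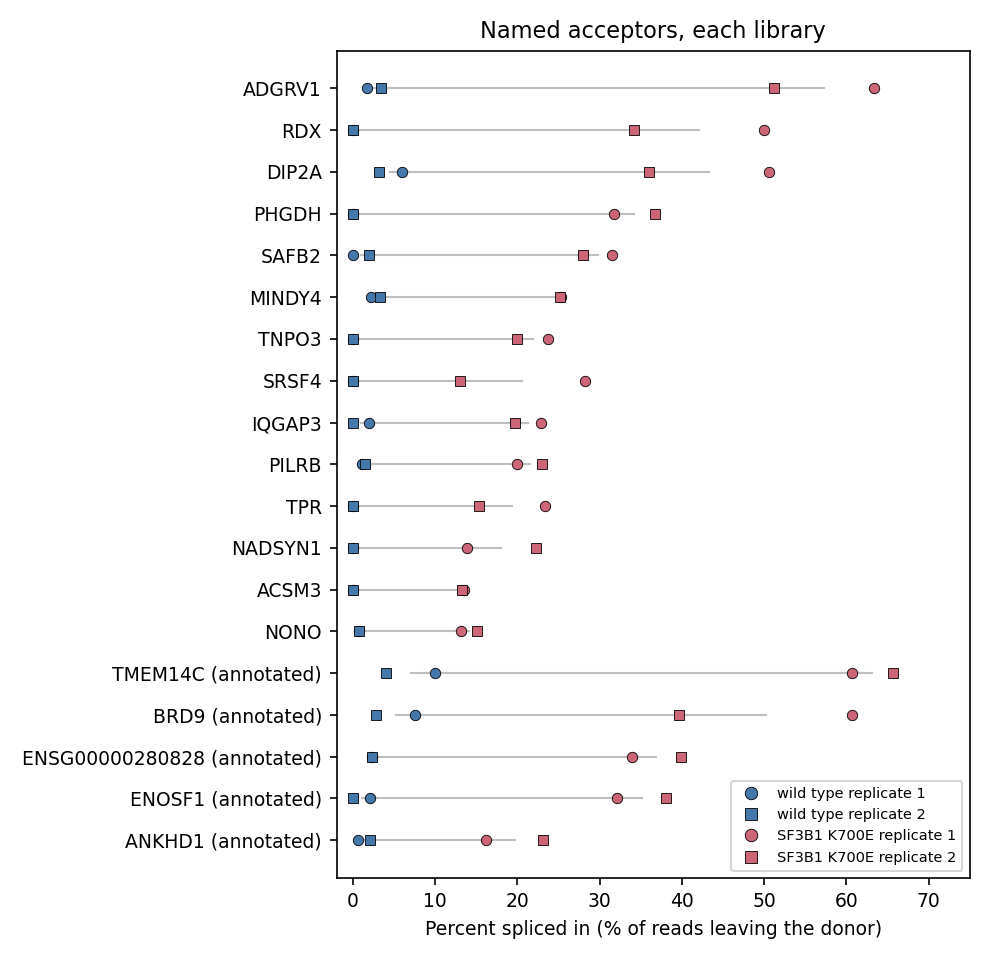
Percent spliced in (x axis, % of reads leaving the donor) of the named acceptors (y axis), each library as a point, in wild type and SF3B1 K700E. Both SF3B1 K700E values lie above both wild-type values, as the naming rule requires, for example in RDX with 0 of 66 wild-type reads against 42.1% ± 11.2.

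Annotated acceptors that rose included genes from the fixed list of mutant SF3B1 targets. TMEM14C, which brings heme precursors into mitochondria, rose from 7.0% ± 4.24 to 63.2% ± 3.47 at the acceptor 14 nt upstream in its 5′ UTR (chromosome 6, 10723242 to 10724555, edgeR adjusted p 0.0260). BRD9, a subunit of the noncanonical BAF remodeller, rose from 5.20% ± 3.37 to 50.2% ± 14.9 at an acceptor inside intron 14 (chromosome 5, 869405 to 870472, edgeR adjusted p 0.0376). ENOSF1, an enolase-superfamily enzyme, rose from 1.05% ± 1.49 to 35.1% ± 4.21 at 15 nt upstream (chromosome 18, 683396 to 685920, edgeR adjusted p 0.00112). ANKHD1, an ankyrin-repeat RNA-binding protein, rose from 1.30% ± 1.04 to 19.6% ± 4.85 at an acceptor 33 nt downstream of the more used one (chromosome 5, 140436258 to 140438493, edgeR adjusted p 0.00283). The pseudogene ENSG00000280828 rose from 2.32% ± 0.0126 to 36.9% ± 4.24 (edgeR adjusted p 0.000190), and its locus overlaps other transcripts, so its gene is uncertain.

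Of the 27 genes on the list of mutant SF3B1 targets, 7 had a tested acceptor 10 to 30 nt upstream. All 7 were higher in both mutant libraries, where chance gives 16.7% for a single site. That value does not hold for sites picked by a minimum of 10 reads over all libraries, which favours sites high in the mutant. Wild-type reads at the 7 sites were at most 7, in TMEM14C, against 38 in SF3B1 K700E. The fixed design named only unannotated acceptors for this list. Of the 7, only 2 were unannotated (MAP3K7 and TTI1), and the others, TMEM14C and ENOSF1 included, were annotated. The median log2 change was 3.16. Over all junctions edgeR called 2 of them, TMEM14C and ENOSF1, and adjusted over the list alone it called 7. MAP3K7, the TAK1 kinase, went from 4.17% ± 5.89 to 60.8% ± 3.54 (edgeR adjusted p 0.174). TTI1, which stabilises ATR and mTOR, went from 5.56% ± 7.86 to 64.4% ± 15, and the dynein light chain DYNLL1 from 11.2% ± 3.0 to 50.3% ± 5.08. The septin SEPTIN6 went from 4.55% ± 6.43 to 44.5% ± 13.7, and the citric acid cycle gene DLST from 2.86% ± 4.04 to 30.4% ± 21.3. Their edgeR adjusted p over all junctions was 1.00 for TTI1, 0.933 for DYNLL1, 0.710 for SEPTIN6 and 0.409 for DLST, so none of these 5 passed there.

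The rise was concentrated in acceptors just upstream of the reference. Unannotated acceptors 10 to 30 nt upstream had a median log2 change of 1.79 (interquartile range 0.38 to 4.50), or 1.32 with the 58 sites at 0 in wild type set to their bound. Of these 226 sites, 141 (62.4%) were higher in both mutant libraries and 11 (4.87%) were lower, where chance gives 16.7% each way for a single site. That value is not a test of the set, since all sites share the same 4 libraries. The read minimum also admitted 58 sites at 0 in wild type against 0 at 0 in the mutant. Acceptors 10 to 30 nt downstream had a median of 0.04 over 109 sites, with 27 up and 22 down. All unannotated acceptors within 100 nt outside the upstream window, these 109 included, had a median of 0.05 over 840 sites, with 178 up and 139 down. Unannotated donors within 100 nt had a median of 0.04 over 529 sites, with 95 up and 83 down. Annotated acceptors 10 to 30 nt upstream had a median of 0.44 over 152 sites, with 61 up and 15 down. Baselines differed, so log2 changes of these classes are not alike in scale. Median PSI went from 2.18% in wild type to 12.7% in SF3B1 K700E at the 226 sites. It went from 8.38% to 11.1% at the 109 sites, from 9.32% to 10.3% over the 840 sites and from 8.83% to 9.48% at the unannotated donors.

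The rise was largest 10 to 25 nt from the reference acceptor. The median fitted log2 change was 2.47 over 64 sites at 10 to 15 nt, 2.30 over 95 sites at 16 to 20 nt and 1.46 over 51 sites at 21 to 25 nt. With the 16, 29 and 11 sites at 0 in wild type set to their bound it was 1.50, 1.34 and 1.22, so these bins differed little. The fitted median was -0.03 over 51 sites at 1 to 4 nt. Bins of under 20 sites lay between, with 0.84 (0.67 at the bound) over 16 sites at 26 to 30 nt and 0.56 over 12 sites at 5 to 9 nt. Farther upstream it was 0.08 over 37 sites at 31 to 50 nt and 0.50 over 56 sites at 51 to 100 nt, where 41.1% were higher and 7.14% lower in both mutant libraries. Among increased unannotated acceptors within 100 nt, 17 of 19 (89.5%) lay 10 to 30 nt upstream, against 209 of 1047 (20.0%) of those not called increased. Fisher's exact test gave an odds ratio of 33.9 and p 2.44e-10. It treats sites as independent, although all share the same 4 libraries and several called ones lie in the same gene, ADGRV1. Its p therefore does not measure the spread between libraries. The other 6 increased unannotated acceptors lay more than 100 nt upstream. Of the 20 increased acceptors in the window, annotated or not, 16 lay 13 to 17 nt upstream.

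**Figure D2:**
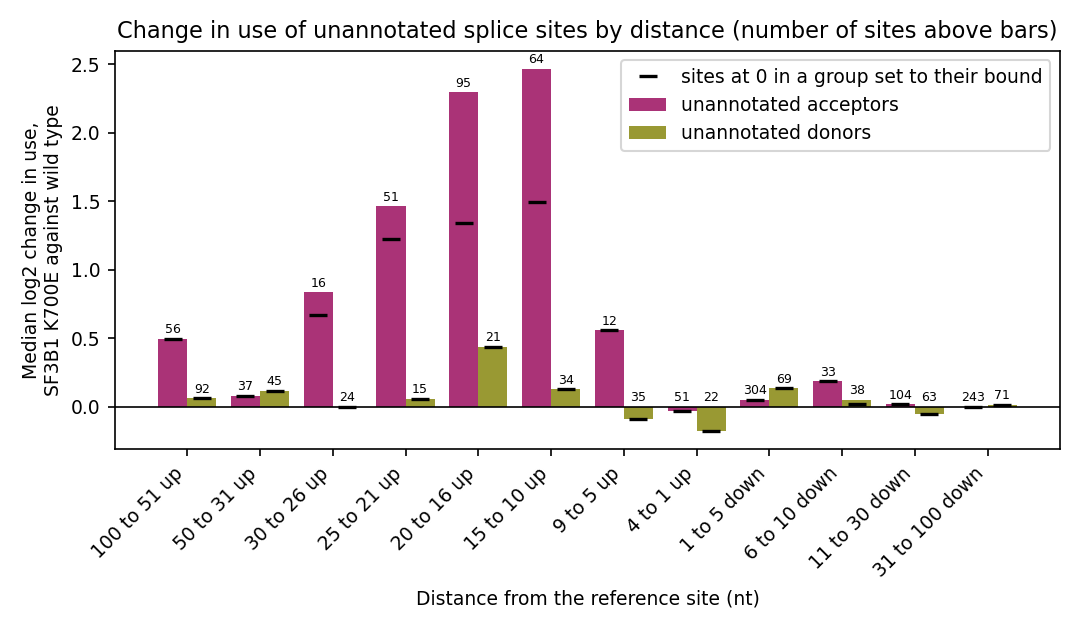
Median log2 change in use, SF3B1 K700E against wild type (y axis), of unannotated acceptors and donors by distance from the reference site in nt (x axis), with the number of sites above each bar. Bars use fitted changes, and black marks set sites at 0 in a group to their bound. Acceptors 10 to 15 nt upstream have the highest median, 2.47 over 64 sites, or 1.50 at the bound, and bars carry no error.

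Most of the increased acceptors in the window would change the reading frame. Of the 20 increased acceptors in the window, 18 lay before a coding exon and 14 of these added a length that is not a multiple of 3. Over all 226 unannotated sites, 165 (73.0%) added such a length, and of the 141 higher in both mutant libraries 98 (69.5%) did. Chance gives 66.7%, and whether these sites lie before a coding exon was not examined.

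Per library, upstream sites took 3.43% and 3.99% of the reads at these sites and their reference acceptors in wild type, and 11.6% and 9.49% in SF3B1 K700E. The Wilson intervals were 3.16 to 3.72% and 3.70 to 4.29% in wild type, and 11.1 to 12.1% and 9.12 to 9.87% in SF3B1 K700E. The means were 3.71% ± 0.396 and 10.5% ± 1.5 (n = 2, exact permutation p 0.333, the smallest this design allows). All unannotated canonical junctions together took 4.35% ± 0.031 of junction reads in wild type and 4.68% ± 0.232 in SF3B1 K700E (n = 2, exact permutation p 0.333). This difference of 0.326 percentage points was 0.162 without SF3B1 K700E replicate 1 and 0.490 without SF3B1 K700E replicate 2. It was 0.152 with multiply mapped reads and 0.0359 over junctions with at least 10 reads.

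**Figure D3:**
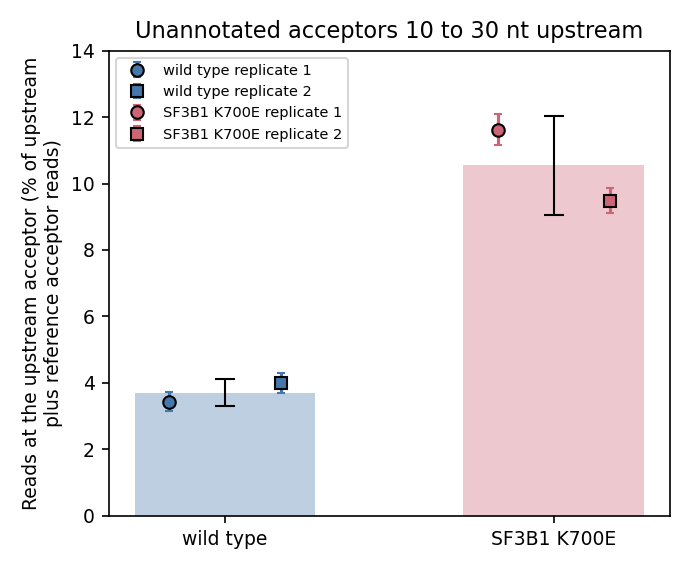
Share of reads at unannotated acceptors 10 to 30 nt upstream, in % of the reads of these sites and their reference acceptors (y axis), for each library (x axis) with 95% Wilson intervals as error bars. The SF3B1 K700E libraries lie at 11.6% and 9.49%, above 3.43% and 3.99% in wild type.

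Few changes in donor choice passed at this depth. Of 22976 junctions in 10661 clusters that share an acceptor, edgeR called 1 donor up and 1 down, against 357 up and 143 down at an unadjusted p under 0.05, and limma voom also called 1 and 1. In MALAT1, a nuclear long noncoding RNA, an unannotated donor joined to 65500911 on chromosome 11 (intron start 65500815) rose from 4.51% ± 1.07 (25 of 544 reads) to 26.6% ± 0.241 (465 of 1746, edgeR adjusted p 0.0274). A donor in TPTE, a phosphatase-like gene with near-identical copies (chromosome 21, 10521695 to 10524579), fell from 22.3% ± 9.29 to 0 of 191 reads, at least 14.2-fold lower (edgeR adjusted p 0.0339), and its gene is uncertain. Neither was called when any 1 library was left out: the count was 0 without wild-type replicate 1, without wild-type replicate 2, without SF3B1 K700E replicate 1 and without SF3B1 K700E replicate 2. At an unadjusted p under 0.05 edgeR then gave 488, 438, 236 and 268 up and 135, 123, 191 and 219 down.

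For the question of elongation, the files hold only where spliced reads lie. Introns over 10 kb took 8.12% ± 0.325 of annotated-junction reads in wild type and 7.84% ± 0.526 in SF3B1 K700E (n = 2, exact permutation p 0.667). The difference of -0.281 percentage points became 0.0914 without SF3B1 K700E replicate 2, and was -0.653 without SF3B1 K700E replicate 1, -0.510 without wild-type replicate 1 and -0.0510 without wild-type replicate 2. The median log2 ratio of reads near the 3′ end over those near the 5′ end, each the outer 1 of 3 equal parts, in 5975 genes of at least 20 kb was 0.69 ± 0.02 in wild type and 0.74 ± 0.12 in SF3B1 K700E (n = 2, exact permutation p 1.00). That difference of 0.05 became -0.04 without SF3B1 K700E replicate 2, 0.13 without SF3B1 K700E replicate 1, 0.06 without wild-type replicate 1 and 0.03 without wild-type replicate 2. Neither of these differences was larger than the SD of the SF3B1 K700E replicates. At a cutoff of 30 kb, introns took 2.34% ± 0.0556 in wild type and 2.17% ± 0.148 in SF3B1 K700E (n = 2, exact permutation p 0.333). There both mutant libraries lay below both wild-type libraries (highest 2.28%, lowest 2.30%). That difference of -0.168 percentage points was slightly larger in size than the SD of the SF3B1 K700E replicates.

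Among called genes above the median expression, LAMA3, COL23A1 and DOCK10 fell the most. LAMA3, which encodes laminin α3, fell from 201 ± 83.8 to 2.77 ± 2.15 CPM (mean ± SD, n = 2). COL23A1, a transmembrane collagen, fell from 93.8 ± 67.5 to 1.88 ± 0.873 CPM. TRDN, which encodes the calcium-store protein triadin, fell from 252 ± 87.4 to 21.8 ± 7.99 CPM, while RYR2, the calcium-release channel that triadin binds, rose from 36.2 ± 12.2 to 166 ± 7.25 CPM. ELMO1, an engulfment and cell motility protein, rose from 12.1 ± 2.29 to 91.5 ± 15.8 CPM. DOCK10, a guanine nucleotide exchange factor, fell from 160 ± 88.2 to 3.78 ± 5.35 CPM.

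Of 10827 genes tested, edgeR called 36 higher and 65 lower in SF3B1 K700E, against 397 higher and 697 lower at an unadjusted p under 0.05. Of the 101, 92 were protein coding and 89 changed by over 4-fold, 35 up and 54 down. The biological coefficient of variation was 21.7%. With all libraries DESeq2 called 63 higher and 154 lower. Without SF3B1 K700E replicate 2 edgeR called 0 higher and 0 lower, with 337 and 609 at an unadjusted p under 0.05, although the log2 changes of LAMA3 (-5.52) and RYR2 (2.25) kept their direction. The edgeR counts were 98 and 176 without wild-type replicate 1, 90 and 227 without wild-type replicate 2, and 88 and 222 without SF3B1 K700E replicate 1.

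The falls had log2 changes (± standard error) of -6.22 ± 0.51 for LAMA3 (chromosome 18, 23689443 to 23956222, edgeR adjusted p 0.000977) and -5.58 ± 0.61 for COL23A1 (chromosome 5, 178237618 to 178590555, edgeR adjusted p 0.00315). DOCK10 had -5.48 ± 0.85 (edgeR adjusted p 0.0164) and TRDN had -3.52 ± 0.35 (edgeR adjusted p 0.00239). FCHO1, which starts clathrin-coated pits, had -3.55 ± 0.46. UNC5B, a netrin receptor, had -2.94 ± 0.37, in a part of chromosome 10 where the other genes within 5 Mb had a median of 0.57 in the same direction. SYNE1, which links the nucleus to actin, had -2.85 ± 0.41, and EPB41L3, a membrane skeleton protein, had -2.43 ± 0.30. UBASH3A, which restrains T-cell receptor signals, had -2.74 ± 0.44 and HCLS1, the hematopoietic cortactin-like protein, had -2.26 ± 0.43.

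The rises had log2 changes of 3.71 ± 0.36 for VPS35L, a subunit of the endosomal retriever (chromosome 16, 19555240 to 19706793, edgeR adjusted p 0.00239), and 2.91 ± 0.30 for ELMO1 (chromosome 7, 36854361 to 37449249, edgeR adjusted p 0.00303). RYR2 had 2.19 ± 0.28, the germ-cell Tudor protein RNF17 had 2.03 ± 0.38 and the ectonucleotidase ENPP3 had 1.12 ± 0.21. The neighbouring pseudogenes ENSG00000259848 and ANKRD20A8P on chromosome 2 had 4.55 ± 0.38 and 3.67 ± 0.41, but have near-identical copies and are uncertain, although both calls held with multiply mapped reads added. ADCY2, an adenylyl cyclase, had 0 wild-type reads and was at least 118-fold higher, chosen for mention after its values were seen.

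**Figure D4:**
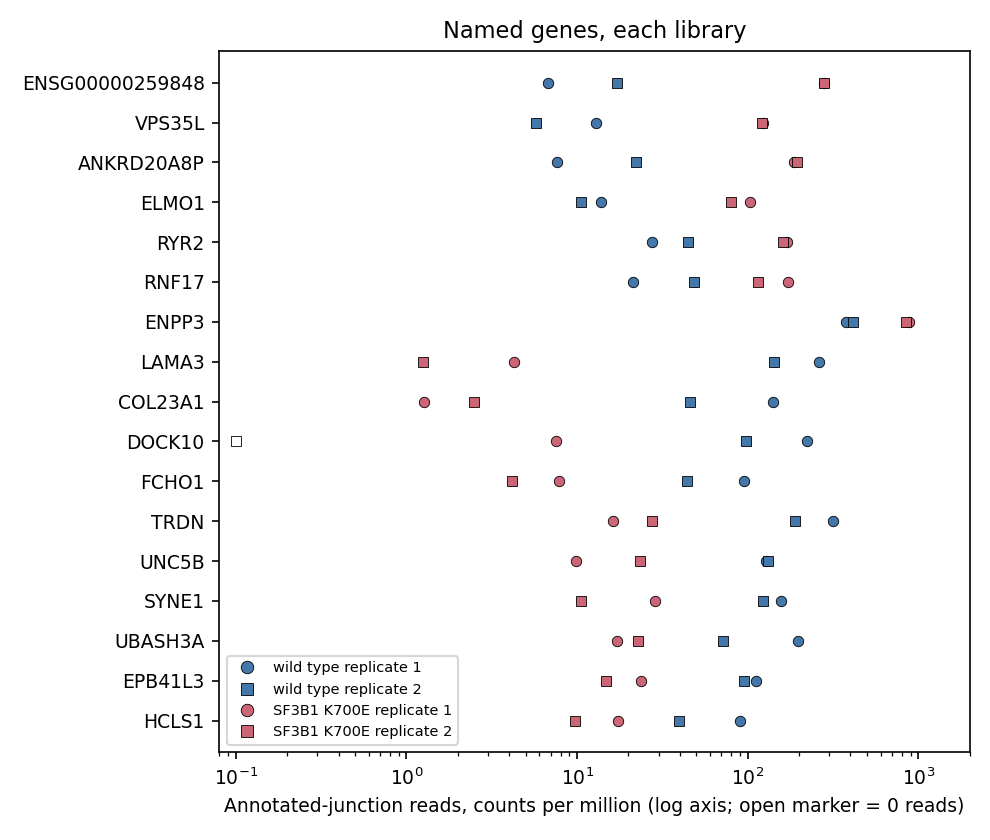
Annotated-junction reads in CPM (x axis, log scale) of the named genes (y axis), each library as a point, with open markers for 0 reads. LAMA3 lies at 201 ± 83.8 in wild type and 2.77 ± 2.15 in SF3B1 K700E, and RYR2 at 36.2 ± 12.2 and 166 ± 7.25.

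No fixed gene list passed as a whole. Of 18 lists 17 could be tested with camera, and 0 passed after adjustment, with 3 at an unadjusted p under 0.05, 0 with an estimated correlation and 0 with fry. Those 3 were the myeloid markers (6 of 13 measured, median log2 -0.50, camera unadjusted p 0.00430, adjusted 0.0731), the SF3B1 targets (26 of 27, -0.26, unadjusted 0.0217, adjusted 0.185) and the R-loop factors (14 of 15, 0.16, unadjusted 0.0343, adjusted 0.194). Camera called the myeloid list down without wild-type replicate 2 (adjusted p 0.0163) and without SF3B1 K700E replicate 2 (0.0107), and the megakaryocyte list up without SF3B1 K700E replicate 1 (0.00555). None of these 3 calls held with an estimated correlation (camera adjusted p 0.914, 0.845 and 0.719) or with fry (adjusted p 0.970, 0.446 and 0.536).

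Erythroid markers had a median log2 change of -0.06 (13 of 19 measured, camera adjusted p 0.770) and heme and iron genes one of -0.13 (18 of 18, camera adjusted p 0.420). The erythroid direction in camera depended on single libraries. It was down without wild-type replicate 1 or SF3B1 K700E replicate 2, and up without wild-type replicate 2 or SF3B1 K700E replicate 1. Megakaryocyte markers had 0.04 (4 of 12, camera adjusted p 0.804) and epithelial markers 0.03 (4 of 12, camera adjusted p 0.991). Only 1 of 12 lymphoid markers was measured, too few for camera. RNA polymerase II elongation genes had 0.13 (26 of 26, camera adjusted p 0.402) and U2 snRNP and spliceosome genes 0.22 (28 of 30, camera adjusted p 0.245). Replication stress and DNA repair genes had 0.13 (24 of 24, camera adjusted p 0.770), mitosis genes 0.11 (16 of 16, camera adjusted p 0.715) and p53 targets 0.12 (14 of 16, camera adjusted p 0.420). The integrated stress response had -0.07 (14 of 14, camera adjusted p 0.429). DNA replication genes had 0.02 (27 of 28, camera adjusted p 0.991), with median and mean above 0 and a camera direction of down. SIN3, HDAC and H3K4 methylation genes had 0.05 (27 of 29, camera adjusted p 0.804) with a mean just below 0. Nonsense-mediated decay genes had -0.01 (10 of 10, camera adjusted p 0.770) with a mean and camera direction above 0. NF-κB targets had 0.03 (11 of 12, camera adjusted p 0.991) with a mean below 0.

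Over all genes edgeR called 1 list member, the megakaryocyte marker and matrix protein THBS1, which rose from 0.606 ± 0.00707 to 12.9 ± 4.98 CPM (log2 4.33 ± 0.63, adjusted p 0.0113), and it was also called when adjusted over the list alone. Adjusted over the list alone, 5 more genes passed, all lower, and none of these passed over all genes. These were the cell cycle kinase CDK1 (-1.23, edgeR adjusted p over its list 0.0160), the mTOR inhibitor DDIT4 (-1.33, 0.0169), the granulocyte colony-stimulating factor receptor CSF3R (-0.96, 0.0228), BRD9 (-1.03, 0.0401) and the T-cell receptor subunit CD3D (-2.30, 0.00272 as the 1 lymphoid gene measured). CDK1 and BRD9 lay in regions of chromosomes 10 and 5 where the uncalled genes had median log2 changes of -0.74 and -0.82.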

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

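Reads over junctions with noncanonical motifs, which entered only 1 alternative setting, took 0.221% of unique junction reads on average in SF3B1 K700E and 0.199% in wild type. This drew attention because both mutant libraries lay above both wild-type libraries, which chance gives in 16.7% of cases, with the lowest mutant value at 0.212% and the highest wild-type value at 0.209%. The gap between these is small beside the spread within either genotype, and no explanation was tested.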

How the results depend on the processing

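Tests with the cluster total as offset, with crossed pairing or without regional runs of genes were chosen after seeing the data; the others were planned. Against 31 increased and 1 decreased acceptors, the numbers called were 13 and 0 with no read minimum (many more junctions tested), 9 and 6 with limma voom, 31 and 0 with a minimum of 30 reads (edgeR, 722 and 49 down unadjusted in these 2), and 43 and 12 with the offset. Donors (1 and 1) numbered 1 and 0 with a minimum of 30 reads (33 down unadjusted), 0 and 0 with multiply mapped reads, where edgeR gave 412 up and 186 down at an unadjusted p under 0.05, and 4 and 3 with the offset. DESeq2 called 63 genes higher and 154 lower. The replicate numbers share no stated origin, and their deviations correlated at -0.21 across genes: the replicate block gave 19 and 0 acceptors (107 down unadjusted), 0 and 0 donors (edgeR, 248 up and 90 down unadjusted), 51 and 85 genes and 0 lists, and the crossed pairing 35 and 1 acceptors and 134 and 326 genes. Without regional runs, 35 and 59 genes and 1 list (myeloid, camera adjusted p 0.0491) were called, the list not with an estimated correlation (0.742) or fry (0.757). The difference in unannotated share (0.326 percentage points) was 0.152 with multiply mapped reads and 0.0359 with at least 10 reads per junction. Leaving out each library gave 5 to 11 increased and 0 to 1 decreased acceptors, 0 to 0 donors each way, 0 to 98 genes higher, 0 to 227 lower, 0 to 1 lists, 85.7 to 100% of acceptors in the window, and differences of 5.78 to 7.90 points in upstream share, 0.162 to 0.490 in unannotated share, -0.653 to 0.0914 in long introns and -0.0386 to 0.129 in the 3′ to 5′ ratio. The cause was not tested. A lone library left in a group was assumed to vary like the other group. Over 238 settings of named junctions 131 kept call and direction, 107 lost the call and 0 reversed, leaving out RLE size factors, which rescale junctions sharing a donor alike, and noncanonical motifs, which raised the acceptor junctions tested only from 23366 to 23393, both of which kept every call; over 216 of named genes these were 193, 23 and 0. At this depth and number of replicates edgeR recovered 17% of simulated 3-fold acceptor changes, so most changes of that size would be missed.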

Other observations

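Tests of regional runs of genes, the tests of depth, and the target list over all canonical junctions were chosen only after the result was seen, and the other tests were planned before it. ADGRV1 carried 3 increased upstream acceptors in 1 transcript of 90 exons. Besides the site in intron 27, an acceptor 21 nt upstream in intron 36 rose from 3.98% ± 1.24 to 53.6% ± 5.65 (edgeR adjusted p 0.000190) and one 15 nt upstream in intron 24 rose from 0.182% ± 0.258 to 18.2% ± 1.44 (edgeR adjusted p 0.00125). Among genes with under 100 cluster reads, LIMD1, a scaffold of RNA-silencing bodies, used an acceptor 241 nt upstream in 0 of 37 wild-type reads and 74.6% ± 4.49 of mutant reads. TPP2, a large cytosolic peptidase, used one 14 nt upstream in 0 of 40 wild-type reads and 53.4% ± 1.09 of mutant reads. These sites were chosen after their values were seen.

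Further called genes were also chosen after their values were seen, and were not tested as groups. Fibronectin FN1 (log2 -2.18), COL6A1 (-1.77) and COL9A2 (-1.61) were lower, while the matrix protein THBS1 (4.33) was higher. DOCK9 (-1.23) was lower and DOCK5 (4.32) higher. On chromosome 18, ANKRD29 (-5.54) fell beside LAMA3, while the nearby OSBPL1A, with 0 wild-type reads, was at least 33.1-fold higher. Other genes within 5 Mb of LAMA3 had a signed median of -0.07, slightly the opposite way.

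The use of upstream acceptors in SF3B1 K700E was weighed against technical sources. Thinning libraries to equal depth leaves a share unchanged on average, so depth was tested through the choice of sites. At 70 sites chosen in 1788093 reads drawn from each library, the lowest mutant share in the reads left over was 2.12 times the highest wild-type share, which argues against depth as the whole cause. At the 27 sites with at least 10 wild-type reads this ratio was 0.990. Their median log2 change was 0.15, with 6 sites higher and 5 lower in both mutant libraries. No rise beyond the spread was seen there. That choice leaves out acceptors silent in wild type and favours sites with high wild-type shares, so it cannot decide about depth. Of the increased unannotated sites in the window 100% had a read with an overhang of at least 30 bases, the lowest being 66, which argues against misaligned read ends. Unannotated donors moved by 2.20% of the median change of these acceptors, which argues against more unannotated splicing of every kind as the whole cause, although after thinning to 3576186 reads distinct unannotated junctions numbered 75330 and 72109 in SF3B1 K700E against 65098 and 64153 in wild type. What stays open is the genotype itself, together with differences that go with it here, such as clone of origin or induction. These libraries cannot tell them apart. Altered branch-point use by SF3B1 K700E remains a hypothesis, which sequence could test.

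Large gene changes were weighed against copy number, since the genotypes may be separate clones. Over the 89 genes changed by over 4-fold, uncalled genes within 5 Mb moved in the same direction by a median log2 of only 0.0557. This argues against copy-number changes that span such neighbours as the source of the set. A gain or loss limited to called genes would not show in uncalled neighbours, so focal copy number stays open. For the 6 inside the runs described next this median was 0.70, although ADCY2, which rose, lay among genes that fell (-1.05). With all canonical junctions counted, 89.9% of the 89 were still called in the same direction, which argues against reads moved to unannotated junctions. Differences between clones that arose before induction stay open, since uninduced cells were not analysed here.

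Part of the genome did move in runs. In windows of 20 uncalled genes, 9 of 526 had a median beyond 0.59, the highest of 100 shuffles of gene order, and all 9 were lower in SF3B1 K700E. On chromosome 5 from 218241 to 43313512 the median log2 change was -0.82, and on chromosome 10 from 43385617 to 70428618 it was -0.74. Between replicates of 1 genotype no stretch of 3 windows moved by more than 0.52, which argues against library noise there. The 95 genes in these 2 regions with too few reads to be tested, which played no part in finding the runs, had a log2 ratio of summed CPM, SF3B1 K700E over wild type, of -0.98, against -0.17 in such genes elsewhere. This is consistent with a copy-number difference, but a regional change in transcription would give the same and was not tested. For the 2 single windows on chromosome 11 library noise may suffice, since a window differed by 0.75 between replicates.

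A lower yield of spliced RNA from genes with the cryptic sites was tested as a hypothesis. Genes with an unannotated upstream acceptor higher in both mutant libraries numbered 126. Their median log2 change was 0.0269 (interquartile range -0.19 to 0.25) over all canonical junctions, against 0.01 in the other genes. Reads at the upstream acceptors by which these genes were picked are part of these totals. That choice can push the median up and hide a loss. Camera gave p 0.315 with the preset and 0.574 with an estimated correlation, and edgeR called 0 of the 126. The quartiles reach past a fall of 0.1, so a small loss in part of them is not excluded. The fixed SF3B1 target list leaned the other way, with a median of -0.26 over annotated junctions, 9 of 26 genes lower and 1 higher in both mutant libraries, and camera p 0.0217 unadjusted and 0.185 adjusted. Over all canonical junctions its median was -0.20 (camera unadjusted p 0.0352, or 0.143 with an estimated correlation). Only 2 of the 26 measured list genes were among the 126, so the list says little about those genes. Annotated upstream acceptors did not count toward the 126. Of the 7 list genes with an upstream acceptor higher in both mutant libraries, only 2 were so at an unannotated one. The rest fell among the other genes here. Whether genes with cryptic sites lose spliced reads on chromatin stays open.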
